A study of Drosophila melanogaster with 9 samples.

How the data were processed

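Transcripts were measured in cells sorted by fluorescence from stage 13 Drosophila melanogaster embryos, laid over 2 h and aged 8 h at 25 °C. The 9 arrays fell into 3 groups of 3. The ap_GFP cells carried GFP under a muscle enhancer of apterous, the slou_RFP cells carried RFP under a muscle enhancer of slouch, and the twi_actin_GFP cells carried an actin-GFP fusion under the twist promoter. Per the labels, each array came from its own sort, labelling and hybridization, so that the spread between arrays of a group includes the spread between sorts. Groups were taken from the sample titles.

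The deposited values were log2 signals per probe set of Affymetrix Drosophila Genome 2.0 arrays. Per the submitters' processing notes they were made with RMA in Partek, which corrects background, normalizes between arrays and summarises the probes of a probe set. The versions and settings were not given in the sources used here. The log2 scale was checked on the values, which ran from 2.28 to 14.64 with array medians of 4.47 to 4.61. RMA gives no detection call, so that a dim probe set has a value but no statement of presence, and differences near the lower end of the scale are compressed. The deposited values were used without further normalization or filter.

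Probe sets were named through the annotation of the array platform as given for this work. Of 16377 probe sets, 11899 were paired with 1 gene, 353 with several genes and 4125 were not listed there and stayed unnamed. The gene ID was found in the RefSeq gene table for 11806 of the 1-gene probe sets, with 0 symbols updated, and no coordinates were used. No gene was named from a probe set with several genes. For each of the 10563 genes with a probe set of its own, the probe set with the highest mean over the 9 arrays stood for the gene. Several probe sets were present for 912 genes, and they were called in opposite directions for 8 genes in ap_GFP against twi_actin_GFP and for 13 in slou_RFP against twi_actin_GFP. Mef2 and Sin3A, which the rule for named genes includes, were not analysed here.

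All 9 arrays entered 1 linear model of 3 group means in limma 3.58.1 under R 4.3.3, with moderated variances (eBayes) and no covariates. Contrasts were ap_GFP minus twi_actin_GFP, slou_RFP minus twi_actin_GFP and ap_GFP minus slou_RFP, and a moderated F test compared the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all 16377 probe sets, and an adjusted p below 0.05 was required for a call. The submitters' own threshold, a fold of at least 1.7 with an unadjusted p below 0.05, was applied beside it. The ± values are standard errors of this fit unless marked SD. Replicate numbers counted sorts within a transgene and entered no main model.

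Genes were named by a rule written before the data were examined. Per contrast it took the 10 largest increases and the 10 largest decreases among called genes whose 3 values in 1 group all lay above the 3 in the other, the genes ap, slou, twi, Mef2 and Sin3A, and up to 4 members of each gene list with the smallest adjusted p. Genes named outside this rule were chosen after their values were seen. These are gcm, hbs, kirre, mid, nau, rols, siz and, for slou_RFP, rst, all against twi_actin_GFP, then MCU and net between the muscle reporters, and the genes given per array for the divergent arrays. The 26 lists were also fixed beforehand. They covered muscle identity transcription factors, pan-mesodermal and myogenic regulators, founder cell and fusion genes, fusion-competent myoblast genes, the sarcomere, muscle attachment and guidance, tendon cells, visceral mesoderm, cardiac mesoderm, fat body, hemocytes, neurons, glia, neuroblasts and sensory precursors, epidermis and cuticle, trachea, endoderm and gut, salivary gland, germ cells, the cell cycle, Sin3A complex and chromatin regulators, the Notch pathway, receptor tyrosine kinase signalling, heat shock and stress, ribosomal proteins and the mitochondrial respiratory chain. Not every member had a named probe set of its own. Measured were 21 of 29 sarcomere genes, without Mhc, Act57B, Tm1 and Tm2 among others, 16 of 24 Notch genes and 8 of 15 pan-mesodermal regulators. Heat shock and stress had 8 of 19, without Hsp83 and the Hsp70 genes among others. The respiratory chain had 12 of 23, without the COX subunits, SdhA, SdhB and SdhC among others. The cell cycle had 16 of 27, without CycA, CycB, Cdk1, stg and polo among others. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists and the 3 contrasts. Camera with an estimated correlation and fry were run as alternatives.

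Both comparisons against twi_actin_GFP share their 3 control arrays. Overlap and correlation were therefore set beside the overlap of independent lists and beside 100 simulations of unchanged groups against shared controls. The pipeline was tested on simulated arrays before use. In the ap_GFP against twi_actin_GFP contrast over 16377 probe sets it called 61.2% of probe sets changed by 1.7-fold, 82.1% of those changed by 2-fold and 92.4% of those changed by 4-fold, with 11 calls among 16177 unchanged probe sets. Over 10563 genes, camera called the 1 shifted list and 0 of the other lists. Genes were simulated independently of each other, so this does not test camera on lists whose genes vary together. With 3 arrays per group the number of arrays limits the precision.

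Alternatives fixed beforehand were subtraction of array medians, a further quantile normalization, omission of the dimmest 40% of probe sets, 1 probe set or the mean of all probe sets per gene, a variance trend with a robust prior, no moderation of variances, only the 2 groups compared, array weights, the replicate number as a block, each array left out in turn, and fold thresholds. Omission of both ap_GFP replicate 3 and slou_RFP replicate 2 was added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.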

Results

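Gene expression was compared between sorted subsets of embryonic muscle cells and cells sorted through a twist reporter. The ap_GFP arrays held cells that express GFP from a muscle enhancer of apterous (ap), a LIM-homeodomain gene of a subset of body wall muscles. The slou_RFP arrays held cells that express RFP from a muscle enhancer of slouch (slou, also S59), a homeodomain gene of another subset. The twi_actin_GFP arrays held cells marked through the promoter of twist (twi), the mesodermal bHLH factor, and served as the common reference. Each group had 3 arrays from independent sorts of stage 13 embryos, when myoblasts fuse into muscles. Purity on resorting was 74% for ap_GFP, 87% for slou_RFP and 95% for twi_actin_GFP, per the labels. Array medians lay between 4.47 and 4.61 on the log2 scale over 16377 probe sets.

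The twi_actin_GFP arrays lay far from the muscle reporter arrays, and the muscle reporter arrays did not separate by reporter. Component 1 held 66.5% of the variance and parted twi_actin_GFP (0.44 to 0.49) from the other 6 arrays (-0.29 to -0.14). Component 2 held 21.4% and set slou_RFP replicate 2 (0.77) and ap_GFP replicate 3 (0.38) apart from the other 7 arrays (-0.28 to -0.05). By correlation each of these arrays was the other's closest array (r = 0.986 across probe sets). For ap_GFP replicate 3 its own group came nearly as close (r = 0.9859 against 0.9863). By the median absolute deviation of log2 differences it lay farther from slou_RFP replicate 2 (0.364) than from every other muscle reporter array (0.241 to 0.257). For slou_RFP replicate 2 the nearest array by this measure was still ap_GFP replicate 3 (0.364, against 0.414 to 0.443 for other muscle reporter arrays). With its own group slou_RFP replicate 2 reached no more than r = 0.970. By contrast ap_GFP replicates 1 and 2 were closest to slou_RFP replicates 1 and 3, with r = 0.997 for both pairs. These correlations run across probe sets, which are not independent replicates.

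**Figure D1:**
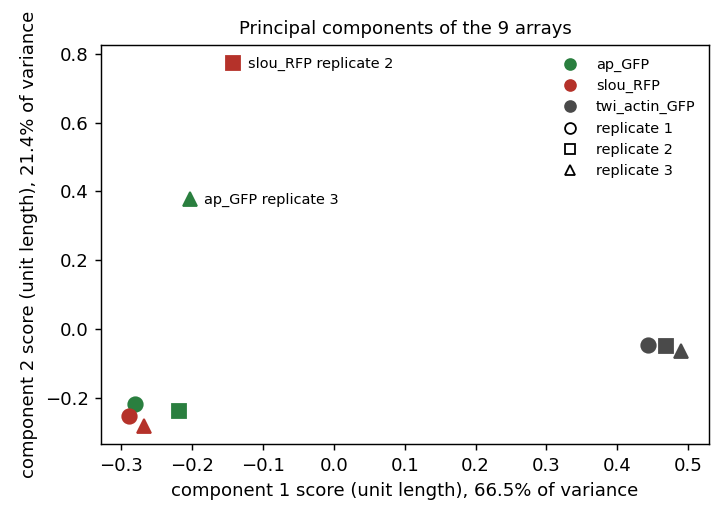
Scores of the 9 arrays on the 2 leading principal components of the log2 signals of all probe sets, coloured by group, with a marker shape for each replicate number. The 3 twi_actin_GFP arrays lie between 0.44 and 0.49 on component 1, and slou_RFP replicate 2 and ap_GFP replicate 3 lie at 0.77 and 0.38 on component 2.

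The genes behind the reporters were read on every array as a check of the labels. Transcripts of ap stood at 8.70, 8.45 and 9.76 on the ap_GFP arrays, at 8.51, 9.16 and 8.53 on the slou_RFP arrays and at 7.18, 7.04 and 7.01 on the twi_actin_GFP arrays. Those of slou stood at 10.77, 10.44 and 10.40 on ap_GFP, at 10.73, 9.97 and 10.77 on slou_RFP and at 7.39, 8.20 and 8.33 on twi_actin_GFP. Against twi_actin_GFP, ap rose by 1.89 ± 0.32 on ap_GFP (limma, adjusted p = 0.00299) and by 1.65 ± 0.32 on slou_RFP (adjusted p = 0.00623), and slou rose by 2.57 ± 0.29 (adjusted p = 0.000308) and 2.52 ± 0.29 (adjusted p = 0.00034). Between the muscle reporters neither gene passed the test. The difference ap_GFP minus slou_RFP was 0.24 for ap (95% interval -0.49 to 0.97, adjusted p = 0.994) and 0.05 for slou (-0.61 to 0.71, adjusted p = 0.996). Levels of ap and slou thus told the muscle reporters from the reference but not from each other, and every statement that follows concerns arrays labelled ap_GFP or slou_RFP. Transcripts of twi itself were lowest on the arrays named after its promoter (mean 7.07, against 9.39 on ap_GFP and 9.40 on slou_RFP) and rose on both muscle reporters, by 2.32 ± 0.21 (adjusted p = 9.27e-05) and 2.33 ± 0.21 (adjusted p = 9.04e-05). The gut gene GATAe, the tracheal gene Gasp and the epidermal gene dy, given below, were also highest on twi_actin_GFP. This reference is therefore named by its label and not taken to be pure mesoderm.

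**Figure D2:**
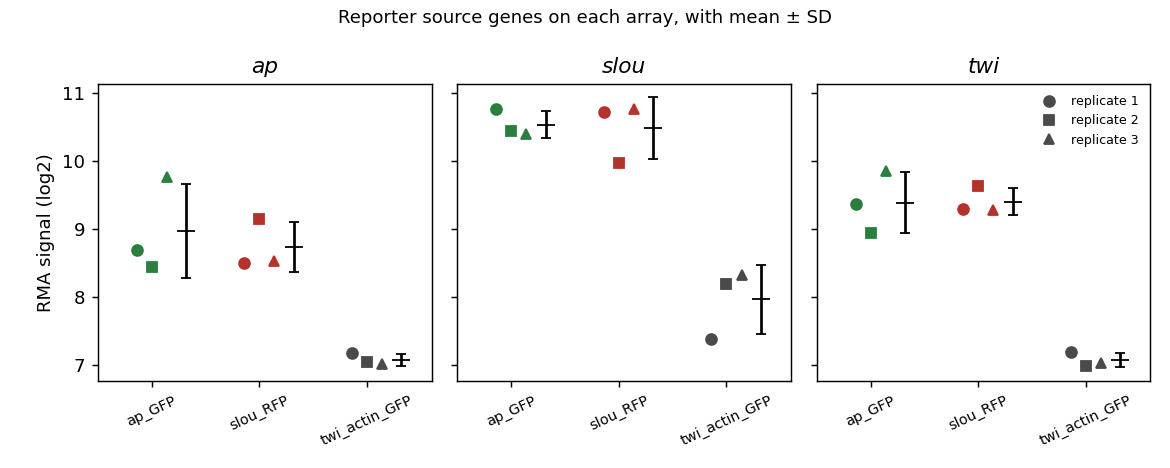
Log2 RMA signal of ap, slou and twi on each of the 9 arrays, with the mean and SD of each group (n = 3) as bars and a marker shape for each replicate number. All 6 muscle reporter arrays lie above all 3 twi_actin_GFP arrays for each gene, and the ap_GFP and slou_RFP arrays overlap.

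The comparison of ap_GFP with twi_actin_GFP asked which transcripts mark the apterous reporter cells against the twist reporter cells. The largest increase among genes of known function was that of lmd, a Gli-family factor needed for the fusion-competent myoblast fate, which rose by 3.62 ± 0.39 (12.3-fold, adjusted p = 0.000237). The adhesion receptor gene sns rose by 3.38 ± 0.54 (adjusted p = 0.0021), sing, which encodes a membrane protein of fusing myoblasts, by 3.18 ± 0.23 (adjusted p = 3.03e-05), and Vrp1, a partner of WASp in actin assembly, by 2.92 ± 0.31 (adjusted p = 0.000213). In the other direction the TGF-beta ligand gene Actbeta fell by 8.35 on the log2 scale (adjusted p = 3.45e-07), to a mean level of 3.95 that lies below the array medians and is not shown to be above background. This fall is therefore read as a lower bound. The crystal cell prophenoloxidase genes PPO2 and PPO1 fell by 6.00 and 5.28 (adjusted p = 1.29e-05 and 4.96e-05).

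The rest of the 10 largest increases were CG7607 (4.38, or 20.8-fold), CG14490 (3.76), CG13833 (2.98), the mitochondrial calcium uniporter gene MCU (2.85), CG12672 (2.85) and EndoU (2.78), with adjusted p between 4.12e-05 and 0.00565. The rest of the 10 largest decreases were CG6733 (-6.77), CG15818 (-4.97), CG2736 (-4.80), the integrin beta subunit gene Itgbn (-4.76), CG10467 (-4.74), CG15347 (-4.71) and mex1 (-4.70), a gene named for midgut expression, with adjusted p between 1.12e-06 and 0.00115. The mean levels of CG15818 (3.09) and Itgbn (3.27) on ap_GFP lay below the lower quartile of every array of that group, so that their decreases are lower bounds too. On each of these genes the 3 arrays of 1 group all lay above the 3 of the other. Named this way, decreases were larger than increases, and 427 called probe sets were lower by 4-fold or more against 80 higher.

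Among the lists, 6 of the 7 measured fusion-competent myoblast genes rose (6 adjusted over the list alone), with a median change of 2.92 (camera, adjusted p = 0.000666). The call was lost with adjusted p = 0.344 with an estimated correlation. Besides the genes above, blow rose by 2.60 ± 0.27 and hbs by 2.17. The list of founder cell and fusion genes, which holds the same 6, had 9 of 14 members higher and 0 lower over all probe sets (9 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.000686, and adjusted p = 0.261 with an estimated correlation). Its other 3 increases were the adhesion gene rst (1.43 ± 0.15), the founder cell adaptor rols (0.78) and siz (1.08), a guanine nucleotide exchange factor of fusion. The founder receptor kirre (0.35, adjusted p = 0.351) and the myogenic factor nau (-0.29, adjusted p = 0.714) did not pass. Notch targets and pathway genes rose in 7 of 16 cases and fell in 1 (11 and 1 adjusted over the list alone; camera, adjusted p = 0.00291, and adjusted p = 0.397 with an estimated correlation). E(spl)mdelta-HLH rose by 2.19 ± 0.30, E(spl)malpha-BFM by 1.01 ± 0.15 and the ubiquitin ligase gene neur by 1.08 ± 0.17, and the Notch antagonist numb fell by 1.18. Without ap_GFP replicate 3 and slou_RFP replicate 2, 14 of the 16 were higher. On these arrays the median deviation of the fusion-competent list from its mean over all 9 arrays was 0.55 and 0.49, against 1.00 to 1.29 on the other 4 muscle reporter arrays and -2.36 to -1.25 on twi_actin_GFP.

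Lists of 7 other tissues were called lower on ap_GFP by camera at its preset correlation, and 0 of the 7 with an estimated correlation. The lists of neurons, neuroblasts, germ cells, salivary gland, tendon cells and cardiac mesoderm were not called. Some lists share members, so that their tests are not independent. The gene srp is on the hemocyte, fat body and gut lists, and svp on the fat body and cardiac lists. Hand is on the visceral and cardiac mesoderm lists, and wb on the visceral mesoderm and attachment lists. In the endoderm and gut list 6 of 7 fell (6 adjusted over the list alone; camera, adjusted p = 0.000356, and adjusted p = 0.261 with an estimated correlation), with GATAe at -3.80, grn at -2.86 and peb at -2.41. Of the hemocyte markers 10 of 15 fell and 1 rose (10 and 2 adjusted over the list alone; camera, adjusted p = 0.000738, and adjusted p = 0.344 with an estimated correlation), among them Glt (-3.24) and the GATA factor srp (-2.45) beside the prophenoloxidases. In fat body 4 of 6 fell and 0 rose (4 and 1 adjusted over the list alone; camera, adjusted p = 0.00467, and adjusted p = 0.261 with an estimated correlation), led by the lipoprotein precursor apolpp (-4.17) and the lipid droplet gene Lsd-1 (-3.29). All 6 tracheal genes fell (6 adjusted over the list alone; camera, adjusted p = 0.00099, and adjusted p = 0.261 with an estimated correlation), with the chitin-binding Gasp at -4.07 and the chitin deacetylase verm at -1.76. Epidermis and cuticle genes fell in 10 of 15 cases (12 adjusted over the list alone; camera, adjusted p = 5.73e-05, and adjusted p = 0.261 with an estimated correlation), with dy at -4.29 and neo at -2.16. Glial markers fell in 6 of 9 (6 adjusted over the list alone; camera, adjusted p = 0.00412, and adjusted p = 0.261 with an estimated correlation), with vir-1 at -1.64 and wrapper at -1.17. Visceral mesoderm markers fell in 4 of 6 (4 adjusted over the list alone; camera, adjusted p = 0.00619, and adjusted p = 0.285 with an estimated correlation), with Hand at -4.16 and the FoxF factor bin at -1.14.

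Cell cycle and replication genes fell in 8 of 16 cases and rose in 1 (10 and 2 adjusted over the list alone; camera, adjusted p = 0.000916, and adjusted p = 0.344 with an estimated correlation). The change was -2.90 for PCNA, -2.51 for the helicase subunit gene Mcm2 and -2.44 for the ribonucleotide reductase subunit gene RnrL. The list deviated by -0.73 on ap_GFP replicate 3 and -0.91 on slou_RFP replicate 2, by -0.37 to -0.12 on the other 4 muscle reporter arrays and by 0.73 to 0.83 on twi_actin_GFP. Without both arrays 4 members were higher and 11 lower. Respiratory chain genes fell in 3 of 12 cases (5 adjusted over the list alone; camera, adjusted p = 0.047, and adjusted p = 0.671 with an estimated correlation), by a median of -0.16 only. This call ended in 9 of 15 other settings, including omission of ap_GFP replicate 1 (adjusted p = 0.0592), ap_GFP replicate 2 (0.0531), ap_GFP replicate 3 (0.0964), slou_RFP replicate 1 (0.0517), twi_actin_GFP replicate 2 (0.142) or twi_actin_GFP replicate 3 (0.0689).

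The measured muscle identity factors and sarcomere genes went both ways. Of 21 identity factors 4 rose and 6 fell (5 and 6 adjusted over the list alone; camera, adjusted p = 0.737), with increases of slou, ap, the T-box gene mid (1.12) and Poxm (1.07 ± 0.12) and decreases of Lim3 (-2.99) and tup (-1.96). Of 21 sarcomere genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera, adjusted p = 0.646), the troponin C gene TpnC41C by 2.77 ± 0.21, Act87E by 1.61 ± 0.24 and the titin-like sls by 1.07 ± 0.18. This list stood at 0.29 on ap_GFP replicate 3 and 0.45 on slou_RFP replicate 2, at -0.37 to -0.06 on the other 4 muscle reporter arrays and at -0.16 to 0.18 on twi_actin_GFP. Without these arrays 7 members were higher and 8 lower. Pan-mesodermal regulators rose in 4 of 8 cases and fell in 1 (4 and 1 adjusted over the list alone; camera, adjusted p = 0.282), among them twi and Him (0.93 ± 0.12). Cardiac genes rose in 3 of 14 cases and fell in 6 (3 and 6 adjusted over the list alone; camera, adjusted p = 0.282), with prc at -3.27, svp at -2.13 and Sur at -1.87. Attachment and guidance genes rose in 2 of 20 cases and fell in 4 (5 and 5 adjusted over the list alone; camera, adjusted p = 0.569), with robo1 at 0.62 and NetB at -1.32. Without ap_GFP replicate 3 and slou_RFP replicate 2 they rose in 5 cases and fell in 7. Tendon markers split 1 higher and 1 lower of 6 (1 and 1 adjusted over the list alone; camera, adjusted p = 0.737), tx (delilah) at 2.02 and shot at -0.69. Of these 1 was higher and 3 lower without ap_GFP replicate 3 and slou_RFP replicate 2. Median, mean and camera's direction differed in sign for 4 lists, namely identity factors, sarcomere, heat shock and ribosomal proteins.

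**Figure D3:**
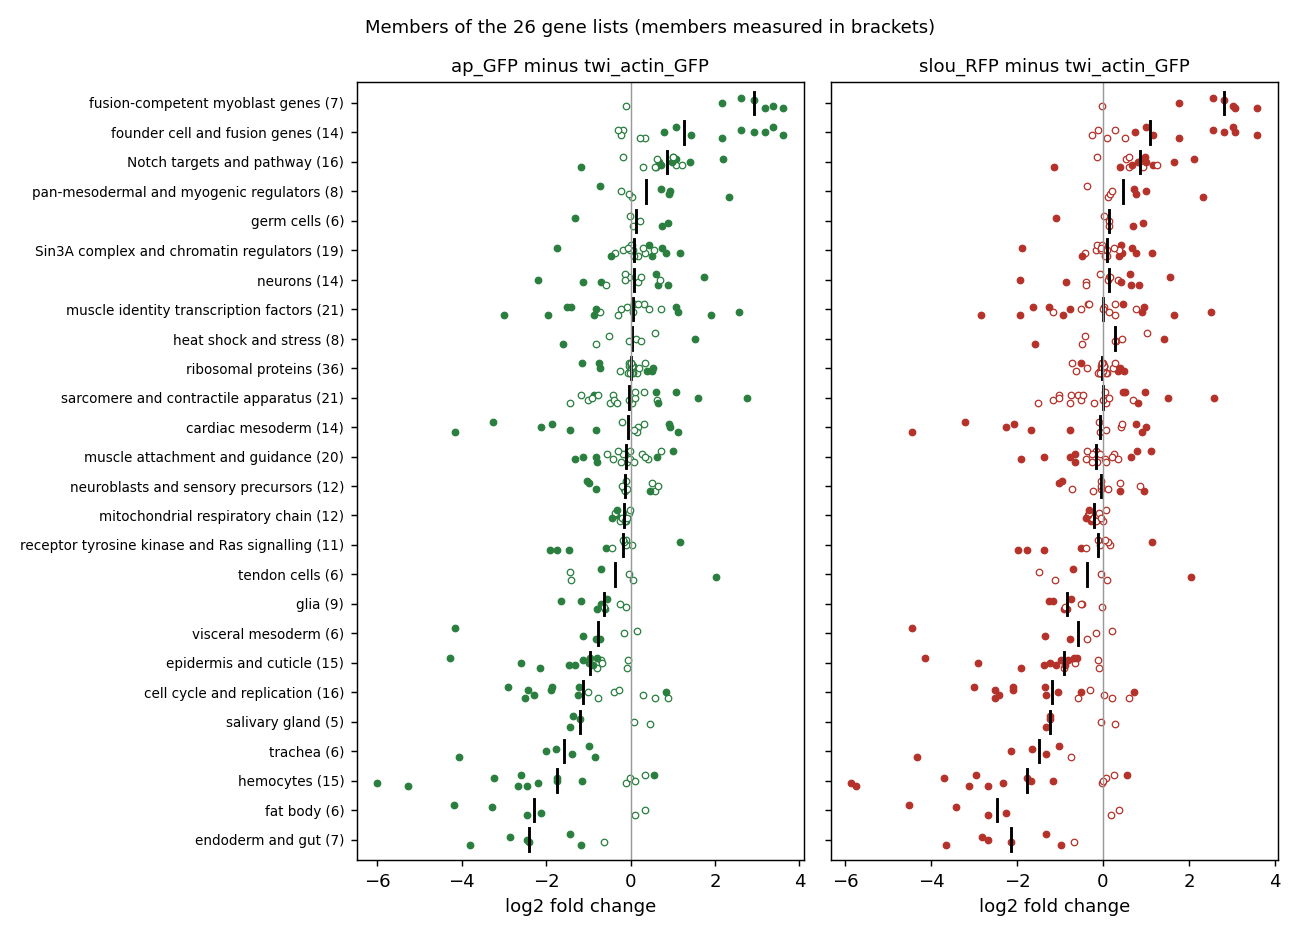
Log2 fold change of each measured member of the 26 gene lists, ap_GFP (left) and slou_RFP (right) against twi_actin_GFP. Filled points had an adjusted p below 0.05 over all probe sets, open points did not, and black bars are list medians. Fusion-competent myoblast genes have the highest medians (2.92 and 2.82), and endoderm and gut (-2.41) and fat body (-2.47) the lowest.

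Over all probe sets, 1601 were higher and 1992 lower on ap_GFP (limma, adjusted p below 0.05), covering 1150 and 1717 genes, and 766 and 1552 passed the submitters' threshold. The balance turned after a further quantile normalization, with 2062 higher and 1846 lower, and with only the 2 groups compared (2356 and 2265). The median change of all probe sets was 0.11. Fewer or more were higher without ap_GFP replicate 1 (1054), slou_RFP replicate 2 (2934, with 2528 lower), twi_actin_GFP replicate 2 (969) or twi_actin_GFP replicate 3 (965), and 3299 were higher and 2729 lower with array weights. Without both ap_GFP replicate 3 and slou_RFP replicate 2, a setting chosen after seeing the data, 3272 were higher and 2696 lower, and 3544 of the 3593 calls were shared.

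The comparison of slou_RFP with twi_actin_GFP asked the same of the slouch reporter cells. Among genes of known function the largest increases were those of fusion genes, with lmd at 3.59 ± 0.39 (12.1-fold, adjusted p = 0.000248), sing at 3.06 ± 0.23 (adjusted p = 3.54e-05) and sns at 3.04 ± 0.54 (adjusted p = 0.00379). The bHLH gene net rose by 3.01 ± 0.33 (adjusted p = 0.000252), Vrp1 by 2.82 ± 0.31 (adjusted p = 0.00026) and Arc1, which encodes a capsid-forming protein, by 2.74 ± 0.15 (adjusted p = 6.58e-06). Actbeta fell by 8.14 on the log2 scale (adjusted p = 4.06e-07), again to a mean level below the array medians, PPO2 by 5.86 (adjusted p = 1.35e-05), PPO1 by 5.74 (adjusted p = 3.19e-05) and apolpp by 4.53 (adjusted p = 1.35e-05). The other large increases were CG7607 (4.13, the largest), CG14490 (3.49), CG13833 (2.99) and EndoU (2.78). The other large decreases were CG6733 (-6.72), CG10467 (-5.03), CG15818 (-4.94), Itgbn (-4.74), CG2736 (-4.73) and CG15347 (-4.56), with the mean levels of CG15818 and Itgbn again below the lower quartile on slou_RFP.

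Fusion-competent myoblast genes rose in 6 of 7 cases (6 adjusted over the list alone; median 2.82; camera, adjusted p = 0.000686, and adjusted p = 0.344 with an estimated correlation), blow by 2.56 ± 0.27 and hbs by 1.77. Founder cell and fusion genes rose in 9 of 14 with 0 lower over all probe sets (9 higher and 1 lower adjusted over the list alone; camera, adjusted p = 7e-04, and adjusted p = 0.261 with an estimated correlation), including rst (1.17), siz (1.01) and rols (0.74). By contrast kirre (0.50, adjusted p = 0.165) and nau (0.29, adjusted p = 0.692) did not pass. The median deviation of the founder cell and fusion list was 0.05 on slou_RFP replicate 2, against 0.61 and 0.64 on the other slou_RFP arrays. In the Notch list 9 of 16 rose and 1 fell (12 and 1 adjusted over the list alone; camera, adjusted p = 0.00223, and adjusted p = 0.391 with an estimated correlation), with E(spl)mdelta-HLH at 2.12 ± 0.30, E(spl)malpha-BFM at 0.98 ± 0.15 and numb at -1.13. In this list 14 were higher without ap_GFP replicate 3 and slou_RFP replicate 2.

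Camera at its preset correlation called 8 lists lower on slou_RFP, against 9 on ap_GFP. On ap_GFP the respiratory chain list was called as well, and that difference was not tested. The lists called lower on slou_RFP held 6 of 7 gut genes (6 adjusted over the list alone; camera, adjusted p = 0.000635, and adjusted p = 0.261 with an estimated correlation), with GATAe at -3.64. Of the fat body genes 4 of 6 fell and 0 rose (4 and 1 adjusted over the list alone; camera, adjusted p = 0.00619, and adjusted p = 0.261 with an estimated correlation), with Lsd-1 at -3.43. Hemocyte markers fell in 10 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone; camera, adjusted p = 7e-04, and adjusted p = 0.344 with an estimated correlation), with Glt at -3.71 and srp at -2.68. Tracheal genes fell in 5 of 6 (6 adjusted over the list alone; camera, adjusted p = 0.00144, and adjusted p = 0.261 with an estimated correlation), with Gasp at -4.32. In epidermis and cuticle 11 of 15 fell (11 adjusted over the list alone; camera, adjusted p = 9.39e-05, and adjusted p = 0.261 with an estimated correlation), with dy at -4.13 and mey at -2.91. Glial genes fell in 5 of 9 (7 adjusted over the list alone; camera, adjusted p = 0.00327, and adjusted p = 0.261 with an estimated correlation), with wrapper at -1.26. Visceral mesoderm markers fell in 3 of 6 (3 adjusted over the list alone; camera, adjusted p = 0.0137, and adjusted p = 0.33 with an estimated correlation), with Hand at -4.44 and bin at -1.34. Cell cycle genes fell in 10 of 16 and rose in 1 (10 and 1 adjusted over the list alone; camera, adjusted p = 0.000666, and adjusted p = 0.344 with an estimated correlation), with PCNA at -3.01, RnrL at -2.52 and Mcm2 at -2.51. Without both divergent arrays, which lay lowest for this list, 4 were higher and 11 lower.

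The remaining muscle lists were not called. Identity factors rose in 5 of 21 cases and fell in 6 (6 and 6 adjusted over the list alone; camera, adjusted p = 0.819), with Poxm at 0.96 ± 0.12, Lim3 at -2.84 and tup at -1.94. Sarcomere genes rose in 6 of 21 with 0 lower over all probe sets (6 and 3 adjusted over the list alone; camera, adjusted p = 0.592), led by TpnC41C (2.60) and Act87E (1.51), and 7 rose and 8 fell without ap_GFP replicate 3 and slou_RFP replicate 2. Pan-mesodermal regulators rose in 4 of 8 (4 adjusted over the list alone; camera, adjusted p = 0.0567), cardiac genes rose in 3 of 14 and fell in 6 (3 and 6 adjusted over the list alone; camera, adjusted p = 0.29), and respiratory chain genes fell in 4 of 12 (4 adjusted over the list alone; camera, adjusted p = 0.0659). Pan-mesodermal regulators were called without slou_RFP replicate 2 (adjusted p = 0.0382) or twi_actin_GFP replicate 3 (0.0477), and respiratory chain genes without twi_actin_GFP replicate 1 (0.0257). Attachment and guidance genes rose in 3 of 20 and fell in 5 (3 and 6 adjusted over the list alone; camera, adjusted p = 0.49), or rose in 6 and fell in 7 without the divergent arrays. Tendon markers rose in 1 of 6 and fell in 1 (1 and 1 adjusted over the list alone; camera, adjusted p = 0.795). Identity factors and sarcomere were the 2 lists whose median, mean and camera direction differed in sign.

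In all, 1826 probe sets were higher and 2120 lower on slou_RFP (limma, adjusted p below 0.05), covering 1195 and 1824 genes, and 633 and 1614 passed the submitters' threshold. A further quantile normalization turned the balance here too, with 2265 higher and 1876 lower. The median change of all probe sets was 0.13. The number higher changed to 1128 without slou_RFP replicate 1, to 960 without twi_actin_GFP replicate 2 and to 901 without twi_actin_GFP replicate 3. Without slou_RFP replicate 2 there were 2609 higher and 2359 lower, and array weights gave 5830 higher and 3398 lower. Without both divergent arrays 3383 were higher and 2772 lower, with 3820 of 3946 calls shared.

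Both comparisons against the reference called largely the same probe sets. Of these, 1204 were higher in both, 1844 lower in both and 0 called in opposite directions, so that 84.8% of the ap_GFP calls were shared with slou_RFP. After a further quantile normalization 1741 were higher and 1659 lower in both. Independent lists of these sizes would share 179 higher and 258 lower. Unchanged groups simulated against shared controls shared 0, which was set in advance, since groups without changes give almost no calls. This 0 is therefore no measure of the overlap expected from the shared controls. Log2 fold changes correlated at r = 0.971 across probe sets, against 0.501 in the simulation, and their covariance was 0.509 against 0.0218, a difference of 0.487. The 3 reference arrays could not be divided into parts of 2 or more, so part of the excess may come from the shared controls. Shared increases numbered 2061 without slou_RFP replicate 2, 741 without twi_actin_GFP replicate 2, 739 without twi_actin_GFP replicate 3, 2623 without both divergent arrays and 3042 with array weights. The F test among the 3 groups called 3385 probe sets, or 2167 without twi_actin_GFP replicate 2, 2083 without twi_actin_GFP replicate 3, 5905 without both divergent arrays and 8128 with array weights.

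**Figure D4:**
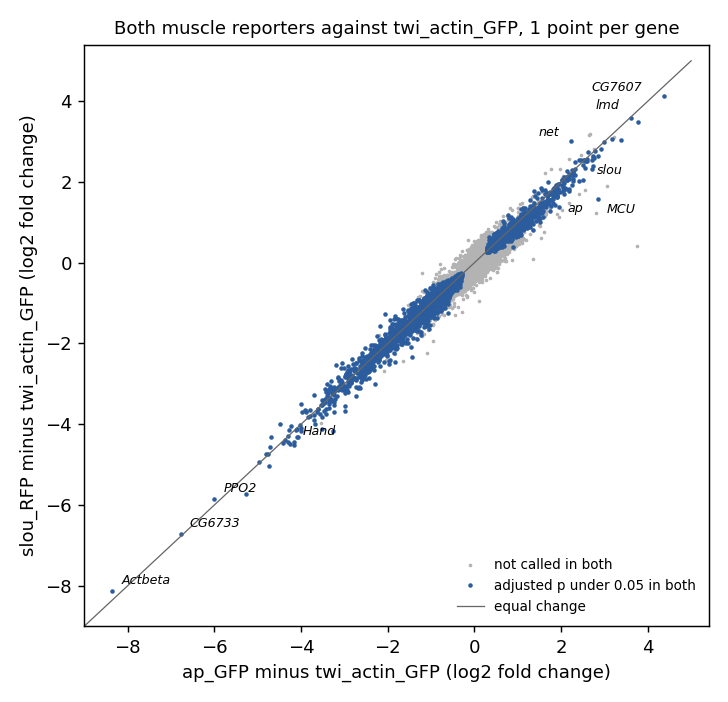
Log2 fold change against twi_actin_GFP of each of the 10563 genes, on ap_GFP (horizontal axis) and slou_RFP (vertical axis), with genes called in both comparisons in blue and the line of equal change. From Actbeta (-8.35 and -8.14) to CG7607 (4.38 and 4.13) the genes called in both lie close to that line.

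The contrast of ap_GFP with slou_RFP tested whether the muscle subsets differed from each other. No gene passed the test. Of 16377 probe sets 0 were called (limma, smallest adjusted p = 0.599), 430 had an unadjusted p below 0.05 where chance alone gives 818.8, and 7 higher and 4 lower passed a fold of at least 1.7 with an unadjusted p below 0.05. Without moderation of variances 0 were called, and 4 and 1 passed the fold threshold. MCU, higher on ap_GFP by 1.26 ± 0.48, and net, at -0.78 ± 0.33, had an adjusted p of 0.994, as did nau at -0.58 (95% interval -1.77 to 0.61). This does not show that the subsets were alike, and neither does a count below chance. Each group held 1 of the divergent arrays (ap_GFP replicate 3 and slou_RFP replicate 2), so that the spread within both groups includes their deviation. With both of these and ap_GFP replicate 1 taken as 1 group, 2430 probe sets had an unadjusted p below 0.05. The intervals that follow carry the same limit. The median 95% interval reached 0.33 log2 units to either side, and for 9668 of 10563 genes (91.5%) it excluded a 2-fold difference, so that larger differences stayed open for the others, ap and slou not among them.

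No list was called between the muscle reporters (camera, smallest adjusted p = 0.0567, for pan-mesodermal regulators, median -0.07), and list medians stayed within 0.21 of 0. Median, mean and camera's direction differed in sign for 5 lists, namely identity factors, sarcomere, visceral mesoderm, trachea and the respiratory chain. Calls appeared when arrays were left out. Without slou_RFP replicate 2 there were 2 lists higher and 2 lower, among them sarcomere (adjusted p = 0.00397), without ap_GFP replicate 3 there were 1 and 2, and without ap_GFP replicate 2, slou_RFP replicate 3 or twi_actin_GFP replicate 1 there was 1 list. Without both divergent arrays hemocyte markers (median 0.17, adjusted p = 0.0155) and epidermis and cuticle genes (0.11, adjusted p = 0.0454) were called higher on ap_GFP by camera. Pan-mesodermal regulators (-0.20, adjusted p = 0.000271), Notch genes (-0.07, adjusted p = 0.00156) and heat shock genes (-0.27, adjusted p = 0.00287) were called lower, while 0 probe sets were called. These calls rest on 2 arrays of each muscle reporter at the preset correlation. An estimated correlation was not run in this setting. With all muscle reporter arrays kept, groupings other than the labelled one gave up to 5 called lists. The calls are therefore not read as differences between the reporters.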

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

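Omission of both ap_GFP replicate 3 and slou_RFP replicate 2 was chosen after seeing the data, and the other processing alternatives were fixed before. Of the 23 called list tests, 22 were called the same way under every alternative run for lists except camera with an estimated correlation, which called 0 lists higher and 0 lower in both comparisons against twi_actin_GFP. Lists were not run with a further quantile normalization, a variance trend, unmoderated variances, only the 2 groups compared or array weights. The exception was the respiratory chain list on ap_GFP (adjusted p from 0.0153 to 0.162). All 40 results of genes with the largest changes, and 139 of 175 other called results of named genes, were called the same way under every alternative run. Among all settings of named genes 4299 comparisons were the same, 223 lost a call, 29 gained a call and 1 reversed, and for lists the numbers were 1178, 32, 36 and 2.

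Counts of increases moved more than counts of decreases. The balance of directions was not stable. More were higher than lower after a further quantile normalization (2062 and 1846 on ap_GFP, 2265 and 1876 on slou_RFP, 1741 and 1659 in both), with array weights, without both divergent arrays, without slou_RFP replicate 2 (2934 and 2528 on ap_GFP, 2609 and 2359 on slou_RFP, but 2061 and 2173 in both) and, on ap_GFP, with only the 2 groups compared (2356 and 2265). With each array left out in turn, probe sets higher on ap_GFP ranged from 965 (without twi_actin_GFP replicate 3) to 2934 (without slou_RFP replicate 2), those higher on slou_RFP from 901 to 2609, those higher in both from 739 to 2061 and those of the F test from 2083 to 4918, at the same arrays. Other such values were 1054 (ap_GFP, without ap_GFP replicate 1), 1128 (slou_RFP, without slou_RFP replicate 1), and 969, 960, 741 and 2167 without twi_actin_GFP replicate 2. Fewer arrays leave fewer degrees of freedom. On ap_GFP, omission of slou_RFP replicate 2 leaves the fold changes unchanged, so that the added calls come from a smaller estimated spread. On slou_RFP the fold changes move as well, and the cause was not tested. Array weights, at 0.114 for slou_RFP replicate 2 and 5.90 for slou_RFP replicate 1, gave 3299 higher and 2729 lower on ap_GFP, 5830 and 3398 on slou_RFP, 3042 and 2681 in both and 8128 by the F test. Without both divergent arrays the counts were 3272 and 2696, 3383 and 2772, 2623 and 2500, and 5905.

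Fold thresholds removed small increases by construction. A fold of at least 1.7 left 766 (unadjusted p), 701 (unadjusted p, no moderation) and 649 (adjusted p) higher on ap_GFP, 633, 564 and 535 higher on slou_RFP, and 560, 506 and 480 higher in both. Between the muscle reporters it passed 7 higher and 4 lower (unadjusted p), and 4 and 1 without moderation. The replicate number as a block gave 1329 higher and 1822 lower on ap_GFP and 1403 and 1917 on slou_RFP.

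Fry called 5 lists higher and 12 lower on ap_GFP, and 6 higher and 13 lower on slou_RFP. Between ap_GFP and slou_RFP 0 lists were called by camera on all arrays. Each array left out in turn gave 0 to 2 higher and 0 to 2 lower, omission of the dimmest 40% of probe sets gave 2 lower, and omission of both divergent arrays gave 2 higher and 3 lower. For the sarcomere and contractile apparatus list, ap_GFP against slou_RFP, the adjusted p ranged from 0.00397 without slou_RFP replicate 2, with the direction reversed, to 0.934 without ap_GFP replicate 1. Without both divergent arrays the epidermis and cuticle list reversed to higher on ap_GFP (adjusted p = 0.0454), and the cause was not tested. The change of lms on slou_RFP went from 0.01 to -0.85, the value also found without slou_RFP replicate 2 alone, so that this array makes the move. A direction was counted as reversed only where the value on all arrays or the alternative was called. Dim probe sets limit what can be seen of small changes, since RMA gives no level of background.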

Other observations

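The tests of ap_GFP replicate 3 and slou_RFP replicate 2 other than the signal range of slou_RFP replicate 2, and the tests of fusion-competent genes and of small increases, were chosen after seeing the result. Splits of the arrays were planned. The 8 lists of this and the next paragraph were not called against twi_actin_GFP by camera on all 9 arrays. Of 11 receptor tyrosine kinase and Ras genes 1 rose and 4 fell on ap_GFP (1 and 4 adjusted over the list alone; camera, adjusted p = 0.0586) and on slou_RFP (1 and 4 adjusted over the list alone; adjusted p = 0.181), with Egfr at -1.92 and -1.98, the FGF gene pyr at -1.47 and -1.37 and the repressor aop at 1.18 and 1.14. On ap_GFP this list was called lower without slou_RFP replicate 2 (adjusted p = 0.0433), twi_actin_GFP replicate 2 (0.0440) or both divergent arrays (0.0423). Heat shock and stress genes split 1 higher and 1 lower of 8 in both (1 and 1 adjusted over the list alone; adjusted p = 0.746 and 0.926), the chaperone gene Hsc70-3 at -1.61 and -1.58 and the cell death gene grim at 1.52 and 1.42, and without ap_GFP replicate 3 and slou_RFP replicate 2 there were 1 higher and 3 lower, and 2 and 3. Chromatin regulators rose in 5 and 6 of 19 and fell in 2 (7 higher and 2 lower, and 6 and 3, adjusted over the list alone; adjusted p = 0.389 and 0.565), Psc at 1.16 and 1.15, trx at 0.74 and 0.69 and esc at -1.74 and -1.89.

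Neuronal genes rose in 4 of 14 and fell in 3 on ap_GFP (5 and 3 adjusted over the list alone; camera, adjusted p = 0.804), and rose in 5 and fell in 2 on slou_RFP (5 and 2 adjusted over the list alone; adjusted p = 0.565), with CadN at 1.74 and 1.55 and cpx at -2.19 and -1.93. Neuroblast genes rose in 1 of 12 and fell in 3, and rose in 2 and fell in 2 (1 and 3, then 2 and 3, adjusted over the list alone; adjusted p = 0.734 and 0.933), and without ap_GFP replicate 3 and slou_RFP replicate 2 the balance turned, with 4 higher and 2 lower, and 5 and 2. Germ cell genes rose in 2 of 6 and fell in 1 in both (2 and 1 adjusted over the list alone; adjusted p = 0.646 and 0.531), aub at 0.89 and 0.94 and vas at 0.74 and 0.70. Salivary gland genes fell in 3 of 5 in both (3 adjusted over the list alone; adjusted p = 0.282 and 0.239), fkh at -1.43 and -1.32. Of 36 ribosomal protein genes 3 rose and 3 fell on ap_GFP, and 3 rose and 1 fell on slou_RFP (3 and 3, then 3 and 1, adjusted over the list alone; adjusted p = 0.898 and 0.889), and 5 rose and 2 fell in both without these 2 arrays.

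On genes chosen after their values were seen, ap_GFP replicate 3 and slou_RFP replicate 2 differed strongly from the other muscle reporter arrays. The guanylate cyclase gene Gyc32E stood at 13.68, 13.57 and 4.77 on ap_GFP replicates 1, 2 and 3, and at 13.59, 6.39 and 13.64 on slou_RFP. The Pax6 gene toy stood at 9.11, 8.77 and 4.52, and at 9.08, 4.20 and 8.99. The Iroquois gene caup stood at 5.49, 7.25 and 10.32, and at 5.86, 9.95 and 5.99, and lms at 5.98, 6.45 and 8.53, and at 5.72, 8.28 and 5.69. Of the identity factors ara was also higher on these arrays (9.50 and 9.16, against 6.06 to 7.07), and nau lower (6.46 and 7.01, against 7.54 to 8.33). The reporter gene ap was highest of the 6 on them (9.76 and 9.16, against 8.45 to 8.70). The reporter gene slou was lowest (10.40 and 9.97, against 10.44 to 10.77), by a small margin for ap_GFP replicate 3. On 5 probe sets both arrays lay over 3 log2 units above each of the other 4, and on 13 below. The heat shock and stress list also set them apart (0.43 and 0.41, against -0.50 to -0.10 on the other 4), as did the small heat shock gene l(2)efl (12.26 and 12.96, against 9.64 to 10.06, and 11.34 to 12.43 on twi_actin_GFP) and the metallothionein gene MtnA (11.16 and 12.24, against 7.87 to 9.55, and 11.98 to 12.06 on twi_actin_GFP). The epidermis and cuticle list did not, with ap_GFP replicate 3 the lowest of the 6 (-0.56) and slou_RFP replicate 2 the highest (-0.26).

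For these arrays, a swap of 1 array between the muscle reporter groups cannot be told apart, since 0 of 9 swaps, and 0 of all 10 arrangements into 3 and 3, put every within-group correlation above every between-group value. A narrower signal range was argued against for ap_GFP replicate 3, whose interquartile range of 4.178 lay within that of the other 4 (4.115 to 4.289). For slou_RFP replicate 2 the range was the narrowest of the 9 arrays (3.807). This array kept 198 probe sets over 2 log2 units away after loess correction, against 224 before. The other 4 arrays had 1 to 5 after correction, which argues against the narrower range as sole cause. A more advanced age of the embryos behind these 2 arrays cannot be told apart either. The lists that lay as it needs (3 of 3), sarcomere genes higher (0.30 and 0.57 against -0.27 to -0.04) and cell cycle and fusion-competent genes lower, were chosen after their values were seen. Later cuticle genes of older embryos left this open, as 37.7% of 106 cuticle family genes (40) were higher on both, above the 19% of all genes but short of most of them. A stress of these sorts and a different set of sorted cells stay open and were not tested.

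Of the 7 genes on the fusion-competent myoblast list 6 rose on both muscle reporters, a list call lost with adjusted p = 0.344 with an estimated correlation in both. The other, gcm, did not pass (-0.12 and -0.02) and is also on the hemocyte and glia lists. A lower share of other mesodermal cells in the muscle sorts was predicted to raise identity and sarcomere genes alike. The largest ratio of their medians to that of the fusion-competent list was 0.0215, with upper quartiles of 0.43 to 0.61. Members of these lists went both ways, on ap_GFP from -2.99 to 2.57 for identity factors and from -1.44 to 2.77 for sarcomere genes. Medians of such mixed lists cannot decide this explanation. Differing purity of the muscle sorts (74% and 87%) was predicted to give a larger rise on ap_GFP, and the small difference between the 2 medians, 0.101, argues against that. It does not address the lower purity of both muscle sorts than of twi_actin_GFP (95%), which stays open. Marked cells that are fusion-competent, or transcripts brought into marked cells by fusion, stay open and were not tested.

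Increases under 1.7-fold outnumbered decreases, 952 against 538 on ap_GFP and 1291 against 604 on slou_RFP. In the dimmest 40% of probe sets, whose median changes were 0.12 and 0.17, against 0.03 and -0.05 in the brightest, a lower background level on the twi_actin_GFP arrays cannot be told apart, since the values were seen before the test was chosen. Outside the dimmest 40%, increases still outnumbered decreases, by ratios of 1.65 and 1.70. That part still holds probe sets below the array medians, which are not shown to be above background. The ratios therefore do not decide whether background is the whole cause.

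Splits of the arrays into other groups were counted. For the comparisons against twi_actin_GFP only 10 splits exist, too few for a share under 0.05. On ap_GFP 1 of 10 splits, the real one, gave 3593 calls (highest other 0) and 1 of 10 gave 12 lists (highest other 10), and on slou_RFP 1 of 10 gave 3946 calls (highest other 0) and 1 of 10 gave 11 lists (highest other 9). Between ap_GFP and slou_RFP 10 of 10 splits gave at least the real 0 calls (highest other 4) and 10 of 10 at least the real 0 lists (highest other 5). These shares were set in advance, since no split can give fewer than 0. For the F test 3 of 100 drawn splits of 280 gave as many as 3385 probe sets (highest other 4780). For shared calls 2 of 100 gave as many as 3048 (highest other 3290). Both shares lie under 0.05, but the real split was not the highest, so chance was not excluded for the 3 groups as labelled. The other splits as large, 2 and 1 in number, all kept the 3 twi_actin_GFP arrays together. Of the drawn splits, 3 besides the real one did so. This points to the division of twi_actin_GFP from the muscle reporters and not to that between ap_GFP and slou_RFP.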
